A study of Mus musculus with 6 samples.

How the data were processed

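MLTC-1 cells were crosslinked with 254 nm ultraviolet light at 400 mJ per cm2, and 20 ug of RNA with an integrity number of 8.35 went into immunoprecipitation, per the labels' protocols. The libraries were eCLIP libraries with adapters that mark PCR duplicates, made from an antibody against ZFP36L2 (2 libraries), from rabbit IgG (1 library) and from the input of each, where the input is a background control of RNA bound by all proteins. Per the submitters' processing notes, the authors used UMI-tools 1.1.1, cutadapt 3.2, STAR 2.7.7a and DESeq2 1.34.0 with the genome build mm10. The notes as used here give no role or order for these tools. How peaks were called, whether on single or pooled libraries, whether the inputs entered the fold change, and how it was normalized are not given in the sources used here.

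The authors deposited a table with 1 row per peak and 3 columns of values. The log2 fold change of ZFP36L2 over IgG was deposited as a log2 value, its direction being that of the table's name, since no header states it. The p-value and the adjusted p-value of each peak were deposited by the authors as −log10 values and were converted back here. The deposited adjusted values differed by at most 0.0099 on the −log10 scale from a Benjamini-Hochberg adjustment of the deposited p-values over all peaks. The table holds no read counts and 0 columns that name a library, so the depth per library and per peak is unknown, no standard error or interval of a fold change can be given, and values of the 4 groups cannot be shown apart. The IgG arm rests on 1 IP library. With 1 library, that arm has no spread between IP libraries, so a call cannot separate the antibody from that library. How the p-values were computed is not given, so which spread they measure, if any between libraries, is unknown. Nothing in the labels says that the libraries came from separate cultures, so any such spread may be technical.

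The planned test of counts could not be applied to fold changes, and the authors' values were taken as deposited, as the plan provided for a table of comparisons. A planned comparison of ZFP36L2 IP with its input was not made, since the table compares ZFP36L2 with IgG. A planned count of AU-rich motifs in peaks was not made, since no genome sequence was used here. A peak was called enriched at an adjusted p under 0.05 and a log2 fold change of 1 or more, and depleted at an adjusted p under 0.05 and a log2 fold change of -1 or less. Only 2 peaks passed the adjusted p without passing the fold change. Gene names and transcript regions are those of the table. Of the 10818 gene names, 10330 (95.5%) were symbols in the RefSeq annotation of assembly GRCm38.p6, the same build as mm10, and 98.5% of the peaks of matched genes with 1 name lay inside the RefSeq gene. A peak with several gene names (561 peaks) counted for each of them, and 8 peaks had no gene name. Neighbouring peaks can touch, as 14872 (26.8%) did, so peaks are not independent. How reads shared by near-identical copies were assigned is not given in the sources used here, which bears on ribosomal protein genes with their many processed copies.

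Regions were compared with two-sided Fisher's exact tests of enriched or depleted peaks against all other tested peaks, adjusted by Benjamini-Hochberg over the 6 regions. Intervals of shares are 95% percentile intervals from 1000 resamplings of genes, since these tests treat peaks as independent. For gene lists, the genes with at least 1 enriched (or depleted) peak were compared with all genes that had a tested peak by two-sided Fisher's exact tests, adjusted over 18 lists. A permutation test with 10000 draws then compared each list with random genes from the same of 9 classes of peaks per gene, adjusted in the same way. The lists cover AU-rich element mRNAs, mRNA decay factors, markers of Leydig, Sertoli, germ cells and macrophages, cholesterol genes, cAMP and protein kinase A signalling, cell cycle, NF-kB and MAPK signalling, stress and hypoxia, apoptosis, nuclear long noncoding RNAs, ribosomal protein, histone, zinc finger and mitochondrially encoded genes and small structural RNAs.

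The lists, the thresholds, most alternative settings and the rule for named genes were fixed before the data were examined. The rule names the 10 genes with the largest log2 fold change among enriched peaks, the 10 with the smallest adjusted p, the 5 with the most negative log2 fold change, the 5 with the most enriched peaks, up to 4 members of each list by adjusted p, and always a set of genes that includes Zfp36l2, Zfp36l1, Zfp36, Lhcgr, Star and Cyp11a1. Some items that the rule names are not reported here. Other genes, and depleted members of lists, were named after their values were seen.

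The list test was checked on simulated data with the 10818 real genes. When the odds of an enriched peak were raised 5-fold, 100 simulations recovered the AU-rich list in 81% of runs, the ribosomal list in 78% and the zinc finger list in 100%, and 15 unchanged lists were called in 1.53% of tests. Every unchanged gene had the same chance of a call there. False calls that follow the number of peaks per gene were therefore not assessed for the list test. The matched permutation gave a p under 0.05 in 4% of simulations without an effect. Alternatives were an adjusted p under 0.01, any log2 fold change of the same sign, a log2 fold change of 2 or more, merged touching peaks, main chromosomes only, 1 peak per gene, depleted peaks as background, matching on peak length in 5 classes or on peaks per gene, and 3′ UTR peaks only. Analyses without the 5 loci with the most enriched peaks and without cardiac muscle genes were added after the data were seen. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.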

Results

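The series measured where on RNA the protein ZFP36L2 could be crosslinked in MLTC-1 cells, a mouse Leydig cell tumour line that makes steroid hormones. ZFP36L2 is a member of a family of CCCH zinc finger proteins known to bind AU-rich elements in mRNA and to speed the decay of the bound transcripts. The assay was eCLIP, in which ultraviolet light links proteins to the RNA they touch, an antibody pulls the protein down, and the attached RNA fragments are sequenced. There were 6 libraries in 4 groups. The antibody against ZFP36L2 gave 2 immunoprecipitation (IP) libraries with 2 matched inputs, and rabbit IgG, the negative control, gave 1 IP library with 1 matched input. The data used here were the authors' values for 55449 peaks in 10818 named genes, each with a log2 fold change of ZFP36L2 over IgG, a p-value and an adjusted p-value. No column held the values of a library, so the sequencing depth behind each peak is unknown, no spread between libraries could be computed, and the direction of the fold change follows the name of the table. Peaks had a median length of 35 nucleotides, and positions are on mouse genome build mm10.

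The comparison of ZFP36L2 with IgG asked which RNA sites the ZFP36L2 antibody recovered over a control antibody. Cyp11a1, which encodes the enzyme that turns cholesterol into pregnenolone at the start of steroid synthesis, had the enriched peak with the smallest adjusted p of all. Of its 35 peaks, 33 were enriched, all of them intronic and between positions 58015982 and 58024448 of chromosome 9. The highest-ranked of them, at 58022019 to 58022055, had a log2 fold change of 5.68 (adjusted p = 5.5e-157) in the authors' deposited table. Neat1, the long noncoding RNA that forms the scaffold of nuclear paraspeckles, was enriched in 44 of its 44 peaks, which spread along the transcript from 5824813 to 5845103 on chromosome 19. The median log2 fold change of these 44 peaks in the authors' deposited table was 3.98, and the peak with the smallest adjusted p, at 5839830 to 5839853, had 5.42 (adjusted p = 3.2e-90).

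**Figure D1:**
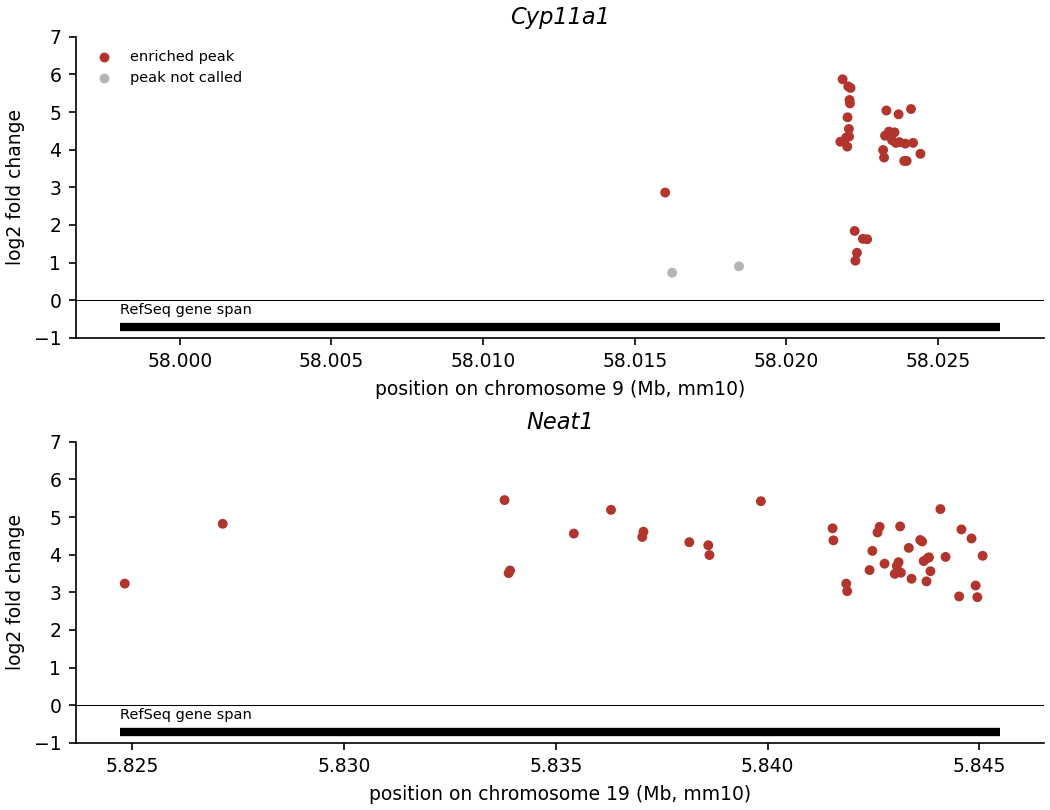
Peaks of Cyp11a1 (chromosome 9, upper panel) and Neat1 (chromosome 19, lower panel) by position in Mb on mm10 (x axis) and log2 fold change of ZFP36L2 over IgG from the authors' deposited table (y axis). Each point is a peak, red where enriched and grey where not called, and the black bar is the span of the gene in RefSeq; 33 of the 35 Cyp11a1 peaks and all 44 Neat1 peaks were enriched.

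A few long stretches held many of the enriched peaks. The overlapping names Gse1 and Galnt2l shared 162 peaks on chromosome 8, of which 68, all intronic and between 120231339 and 120539438, were enriched with a median log2 fold change of 4.33 in the authors' deposited table. Pgbd5, a gene derived from a piggyBac transposase, had 50 of 77 peaks enriched, all in introns. Nckap5 had 26 of 68 peaks enriched and 7 depleted. Together with Neat1 and Cyp11a1, these 5 loci held 222 enriched peaks (18.0%), counting each peak that carries any of these names, whereas the 5 gene names with the most depleted peaks held 1.59% of the depleted ones.

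The largest log2 fold change in the authors' deposited table, 7.05 (adjusted p = 3.1e-47), belonged to an intronic peak of Ppara, the nuclear receptor that drives fatty acid oxidation genes, at 85738587 to 85738631 on chromosome 15. Ppara had 11 enriched peaks among 27. Among the next genes by size were 3′ UTR peaks of Sec63, an endoplasmic reticulum translocation factor, Hipk2, a nuclear kinase, and Bsg, the basigin partner of monocarboxylate transporters, with 6.72, 6.44 and 6.22 in the authors' deposited table. Intronic peaks of Spidr, a homologous recombination scaffold, Pms1, a MutL homologue, Pgbd5 and Bysl, a small ribosomal subunit assembly factor, had log2 fold changes of 6.65, 6.50, 6.32 and 6.25, per the authors' deposited table. The group was completed by Gm37352, with 6.43 in a peak of the class other, and Tcaf1, which encodes a TRPM8 channel-associated protein, with 6.39 in a coding peak of the authors' deposited table. Sec63 and Spidr each had 1 enriched and 1 depleted peak, among 5 and 10, and Hipk2 had 7 enriched and 3 depleted among 39. The other genes of this group had no depleted peak.

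Several of the best-supported peaks lay in coding sequence. Calr, which encodes the calcium-binding chaperone calreticulin, had 4 of 4 peaks enriched, all coding, with a top adjusted p of 6.6e-70 at a log2 fold change of 3.55 in the authors' deposited table. Together they covered 67 nucleotides. Hsp90ab1, the constitutive cytosolic HSP90, had 4 of 5 peaks enriched (best adjusted p = 2.8e-49 in the authors' deposited table). These 4 peaks lay within 1 short stretch, covering 31 nucleotides from 45570491 to 45570521 on chromosome 17. All 8 peaks of Cdk11b, a kinase of transcription and splicing, were enriched, with a median of 3.23 in the authors' deposited table. They covered 100 nucleotides between 155638529 and 155640749 on chromosome 4. Ankrd11, a chromatin regulator, had 2 enriched and 4 depleted peaks among 26, the best at 4.22 (adjusted p = 4.4e-51) in the authors' deposited table. Nrbp2, a pseudokinase gene, had 1 peak, coding, at 5.35 (adjusted p = 6.2e-41), and the imprinted long noncoding RNA Meg3 had 3 of 4 peaks enriched and 1 depleted, the best at 3.55 (adjusted p = 4.8e-49), in the authors' deposited table. A peak assigned jointly to Gm28006 and Neat1 was the last of the 10 gene names ranked by their best adjusted p (2.1e-40 in the authors' deposited table). It is 1 of the 44 Neat1 peaks described above.

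As deposited, peaks called lower with ZFP36L2 than with IgG were more numerous than those called higher and more evenly spread over genes. The most negative log2 fold changes in the authors' deposited table were -6.94 in an intron of Afg1l, a mitochondrial ATPase gene, and -6.89 in the 3′ UTR of Pde5a, the cyclic GMP phosphodiesterase. An intronic peak of Prkg1, the cyclic GMP-dependent protein kinase, followed at -6.79, and peaks in an intron of Coro7, a coronin, and in the 3′ UTR of Tm9sf3, a membrane protein gene, both stood at -6.62 in the authors' deposited table. Tm9sf3 was depleted in 11 of its 13 peaks and Afg1l in 8 of 12.

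Across the table, 1231 peaks (2.22%) were enriched and 3019 (5.44%) were depleted at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. Enriched peaks fell in 545 genes (5.04% of those tested), 363 of them with 1 enriched peak, and depleted peaks in 1876 genes (17.3%). Both kinds occurred in 107 genes. The median log2 fold change over all peaks in the authors' deposited table was -1.06, and 76.2% of values lay below 0. Of the peaks with a log2 fold change of at least 3 in size, 721 were higher and 2627 lower as deposited (21.5% higher), but 1553 were higher and 365 lower (81.0% higher) once all values were centred on their median. Of these scalings, the excess of lower peaks held for the deposited one only. The count of depleted peaks dropped to 1864 at an adjusted p under 0.01.

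**Figure D2:**
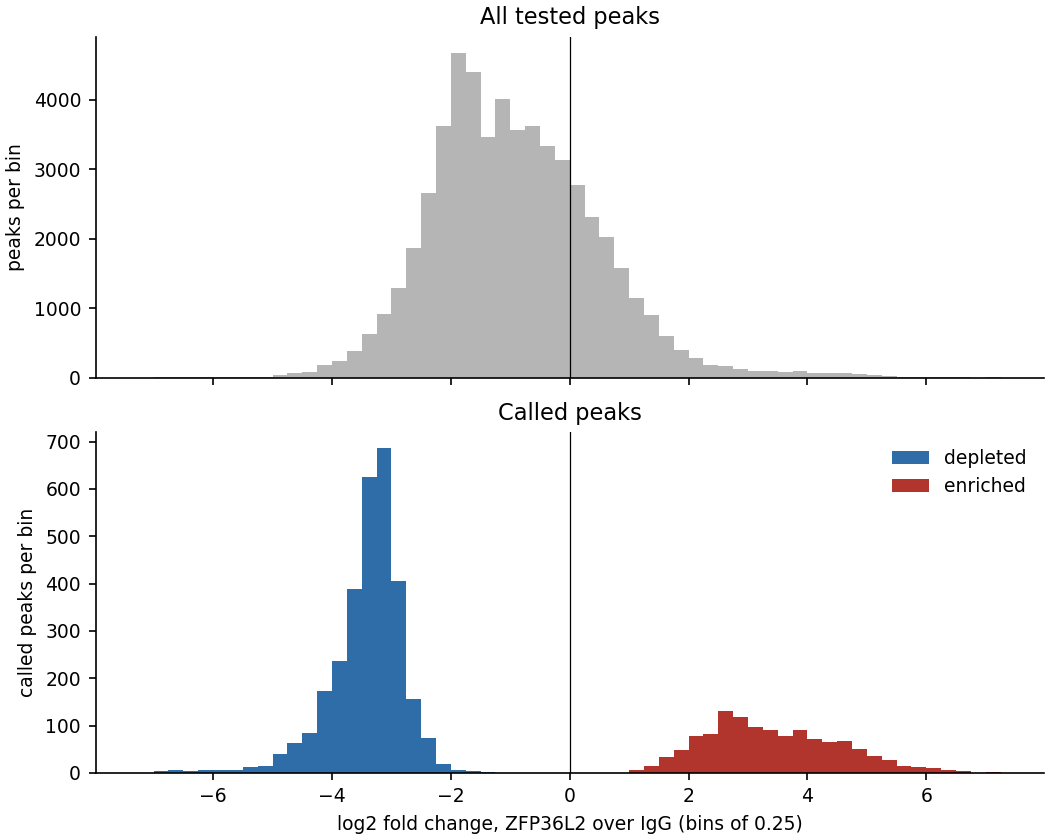
Number of peaks (y axis) by log2 fold change of ZFP36L2 over IgG in bins of 0.25 (x axis), for all 55449 peaks (upper panel) and for the 1231 enriched and 3019 depleted peaks (lower panel, red and blue). The median of all peaks is -1.06 and 76.2% of values lie below 0.

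The transcript region of the enriched peaks was compared with that of all other tested peaks to see which parts of transcripts the ZFP36L2 antibody recovered. Enriched peaks lay in 3′ UTRs less often than other peaks, with 110 peaks (8.94%, 95% interval 6.38 to 12.1 from resampling genes) against 13.7% (odds ratio 0.618, two-sided Fisher's exact test, adjusted p = 3.09e-06). The 110 peaks fell in 75 genes, among them Sec63, Hipk2, Bsg, Ier2 and Lyz2. Coding sequence held 482 enriched peaks (39.2%, interval 32.5 to 46.8) against 36.9% of other peaks (adjusted p = 0.171), and introns held 508 (41.3%, interval 31.5 to 50.2) against 42.3% (adjusted p = 0.466). The 5′ UTR share was 3.17% (interval 2.05 to 4.45) against 2.19% (39 peaks, adjusted p = 0.0606). Peaks of the class other, which includes Neat1 and Meg3, made up 7.23% (interval 2.68 to 15.1) against 4.71% (89 peaks, odds ratio 1.58, adjusted p = 0.00033). That interval, from resampling genes, includes the share of the other peaks. Of the enriched peaks, 3 were in miRNAs (adjusted p = 0.197).

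Depleted peaks had another distribution. Introns held 1651 of them (54.7%, interval 52.3 to 56.8) against 41.6% of the remaining peaks (odds ratio 1.69, adjusted p = 4.75e-44), and coding sequence held 768 (25.4%, interval 23.4 to 27.4) against 37.7% (odds ratio 0.565, adjusted p = 2.84e-43). The 3′ UTR share was 12.1% (interval 10.6 to 13.6) against 13.7% (364 peaks, adjusted p = 0.0222).

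Some of these shares changed when each gene was counted once or the loci with many peaks were left out. The setting with 1 peak per gene kept the peak with the smallest adjusted p, and ties went to the larger log2 fold change. A gene was counted by that peak alone, which left 525 enriched. The coding share of enriched peaks was then 50.1% against 34.6%. The intronic share was then 28.0% against 35.7%. In the class other, the share was 5.90% against 11.6%, compared with 7.23% against 4.71% over all peaks. Most of that turn came from the other peaks, whose share rose. Without the 5 loci named above, an alternative chosen after the data were seen, the class other held 4.46% against 4.73%. The 5′ UTR share was 3.87% against 2.20% there.

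**Figure D3:**
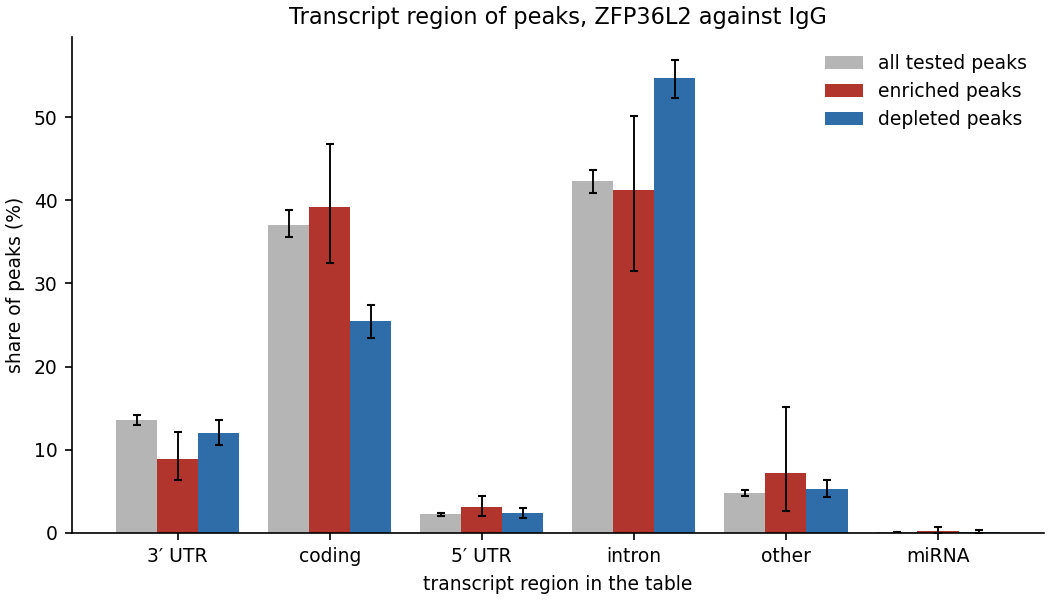
Share of peaks in percent (y axis) by transcript region as named in the authors' table (x axis), for all tested peaks (grey), enriched peaks (red) and depleted peaks (blue). Error bars are 95% intervals from 1000 resamplings of genes; enriched peaks had a 3′ UTR share of 8.94% and depleted peaks an intronic share of 54.7%.

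Gene lists drawn up from textbook knowledge were used to ask which groups of transcripts carried enriched peaks. The genes of the ZFP36 family gave no direct reading, as Zfp36, Zfp36l1 and Zfp36l2 had no peak in the table. Of 50 tested genes on the list of mRNAs with AU-rich elements, 6 (12%) had an enriched peak against 5.01% of other genes (two-sided Fisher's exact test, adjusted p = 0.161 over the 18 lists), and the adjusted permutation p at the same number of peaks per gene was 0.0819. Ier2, an immediate early gene, was enriched in its 3′ UTR (2.99), Dusp1, a MAP kinase phosphatase, in coding sequence (3.80), Egr1, an immediate early transcription factor, in an intron (4.09), and Hif1a, the hypoxia-inducible factor, in its 5′ UTR (3.87), all per the authors' deposited table. Another 8 members had a depleted peak, among them Plk2, Klf4 and Pim1.

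Of 18 tested Leydig cell markers, 3 had an enriched peak (adjusted p = 0.169). They were Cyp11a1, Lhcgr, the receptor for luteinizing hormone, and Prlr, the prolactin receptor. The Lhcgr peak was 1 of 16 and lay at 88722146 to 88722224 on chromosome 17, inside the RefSeq span of the gene, in the class other, with a log2 fold change of 3.93 (adjusted p = 1.1e-14) in the authors' deposited table. The other 15 Lhcgr peaks were intronic and not called. The Prlr peak, in the 5′ UTR, had 2.53 (adjusted p = 0.034) in the authors' deposited table, and 1 of 20 Prlr peaks was enriched. Star, whose product carries cholesterol into mitochondria, had 3 peaks with values of 0.50, -0.89 and 0.00 in the authors' deposited table, none of them called. Gata4, Nr2f2 and Pdgfra each had a depleted peak.

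Cholesterol genes had peaks in both directions. Among 32 tested members of cholesterol synthesis and uptake, 4 had an enriched peak (adjusted p = 0.169) and 6 a depleted one (adjusted p = 0.990). The enriched ones included Fdft1, which encodes squalene synthase (5.07, coding), Osbp, the oxysterol-binding protein (4.52, coding), and Abca1, the cholesterol efflux pump (2.25, intronic), in the authors' deposited table. Insig1, the endoplasmic reticulum anchor of the SREBP pathway, was depleted in 6 of 6 peaks, down to -5.35 (adjusted p = 2.3e-09) in the authors' deposited table. Dhcr7, the final reductase of cholesterol synthesis, reached -4.60 in the authors' deposited table, while Mvd, Srebf1 and Srebf2 also had depleted peaks.

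In cAMP and protein kinase A signalling, which carries the luteinizing hormone signal, 5 of 39 tested genes had an enriched peak (adjusted p = 0.161) and 12 a depleted one (adjusted p = 0.202). The anchoring proteins Akap9, Akap12 and Akap11 had best log2 fold changes of 5.09, 3.02 and 2.26, and Gnas, the stimulatory G protein subunit, 1.80, in the authors' deposited table. Prkaca, the catalytic subunit, also had 1 enriched peak. Depleted members included Creb1, Crem, Prkar1a, Sik1 and Pde4d. Of 41 mRNA decay factors, 3 had an enriched peak (adjusted p = 0.801) and 9 a depleted one (adjusted p = 0.739). Cnot1, the scaffold of the CCR4-NOT deadenylase, and Pabpc1, the cytoplasmic poly(A)-binding protein, were in both groups, with best enriched values of 2.87 and 3.57 in the authors' deposited table. Tnrc6b, a GW182 protein of microRNA silencing, had an enriched intronic peak at 1.82 in the authors' deposited table.

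Ribosomal protein genes carried enriched peaks more often than other genes, in 7 of 42 tested members (16.7% against 4.99%, adjusted p = 0.0414), and at the same number of peaks per gene (adjusted permutation p = 0.0072). The best were Rps15, Rps7, Rpl32l and Rps2, with log2 fold changes of 4.55, 4.11, 2.77 and 2.33 in the authors' deposited table, and 4 other members had a depleted peak. Zinc finger protein genes carried them less often, in 1 of 211 members (0.474% against 5.13%, adjusted p = 0.00648), although the adjusted permutation p at the same number of peaks per gene was 0.0552. That member was Zfp106, with 3 of 29 peaks enriched and a best value of 3.23 in the authors' deposited table. Sertoli cell markers had enriched peaks in 2 of 3 tested members (adjusted p = 0.0441, adjusted permutation p = 0.0552), namely Clu, the secreted chaperone clusterin (2.34), and Ctsl, the lysosomal protease cathepsin L (3.14), per the authors' deposited table. Both are also made by many other cell types. At an adjusted p under 0.01 or a log2 fold change of 2 or more, neither the ribosomal nor the Sertoli list passed.

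**Figure D4:**
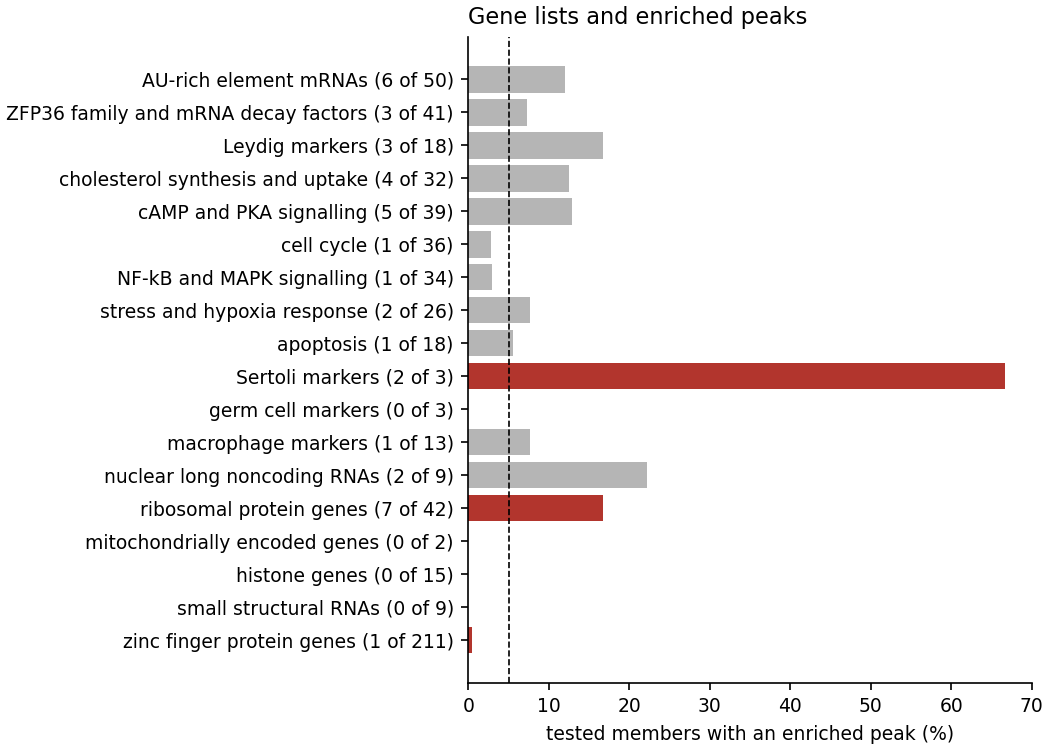
Share of tested members with an enriched peak in percent (x axis) for each of the 18 gene lists (y axis, with the number of members with an enriched peak and the number tested). Red bars have an adjusted Fisher p under 0.05 and the dashed line is the share over all tested genes, 5.04%; the ribosomal list stands at 16.7% and the zinc finger list at 0.474%.

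The remaining lists did not pass the test for enriched peaks. Neat1 and Meg3 were the 2 of 9 nuclear long noncoding RNAs with an enriched peak (adjusted p = 0.169), and Kcnq1ot1, which silences an imprinted domain, was depleted in 4 of 6 peaks. Stress and hypoxia genes had enriched peaks in 2 of 26 members, Hif1a and Hsp90ab1 (adjusted p = 0.759), and no depleted peak (adjusted p = 0.194). Enriched peaks occurred in 1 of 36 cell cycle genes (Mcm2, a replicative helicase subunit, 4.52 in the authors' deposited table, with 1 enriched and 4 depleted peaks among 11), 1 of 34 NF-kB and MAPK genes (Dusp1), 1 of 18 apoptosis genes (Cflar, the caspase-8 inhibitor, 1.80) and 1 of 13 macrophage markers (Lyz2, lysozyme, 3.34). No enriched peak was found among 3 germ cell markers, 15 histone genes, 9 small structural RNAs and 2 mitochondrially encoded genes. For depleted peaks, none of the 18 lists passed, with a lowest adjusted p of 0.194. Adjusted over the list alone, the count of genes with an enriched peak was the same in 17 lists and was 8 for ribosomal protein genes.

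Genes of cardiac muscle, a list drawn up after the values were seen, held 58 of the 1231 enriched peaks in 16 genes. Without that list, 36.7% of 1173 enriched peaks were coding, against 35.7% of other peaks.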

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

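The alternatives without the 5 loci and without cardiac muscle genes were chosen after the data were seen. The count of 1231 enriched peaks ranged from 1009 to 1233 over 7 alternatives, and that of depleted peaks moved in 1, to 1864 at an adjusted p under 0.01. The 3′ UTR deficit kept its direction and adjusted p under 0.05 in all 8 alternatives, with a log2 odds ratio from -0.77 to -0.37. The coding excess, 0.14 as reported, passed with 1 peak per gene (0.93), against depleted peaks alone (0.92) and without the 5 loci (0.63), where the intronic value, -0.06 as reported, passed too (-0.51, -0.78 and -0.58). Depleted peaks had a low coding and a high intronic share of their own, so the values against them do not describe enriched peaks alone. The intronic value turned to 0.0354 when matched on peak length and to 0.0023 without cardiac genes, neither passing. The 5′ UTR excess passed at an adjusted p under 0.01 (0.72), a log2 fold change of 2 or more (0.66), matched on length (0.59), without the 5 loci (0.85) and without cardiac genes (0.61). The class other turned to -1.05 with 1 peak per gene and -0.0754 without the 5 loci, which hold 44 of its 89 enriched peaks. Of the 3 lists that passed, 1 did so at an adjusted p under 0.01, 1 at a log2 fold change of 2 or more, 1 when matched on peaks per gene, and 0 with 3′ UTR peaks only. In that last setting, 7 lists whose difference from other genes was positive as reported had no member with an enriched peak, so that their value in percentage points is set by that count of 0 (adjusted p = 1 for each): decay factors -2.19, Leydig -2.18, cAMP -2.19, stress -2.18, apoptosis -2.18, Sertoli -2.18 and ribosomal -2.18. Apoptosis, with no member left at a log2 fold change of 2 or more, stood at -4.76 there (adjusted p = 1). Apart from the 5 loci, the cause was not tested. Of the peaks selected by the naming rule, 1 per gene, 5 lost their call at an adjusted p under 0.01 (Abca1, Akap11, Clu, Prlr and Tnrc6b) and 3 at a log2 fold change of 2 or more (Cflar, Gnas and Tnrc6b). Peaks mentioned besides that lost theirs at an adjusted p under 0.01 include those of Prkaca, Gata4, Pdgfra and Srebf1 and the depleted peak of Meg3. No paired analysis was possible because the table gives no values per library. For the same reason, fits of counts, other normalizations, left-out replicates and IP over input were not run, nor were motif tests, which need a genome sequence, matching on mean signal or a repeat filter. Depth is unknown, so a peak that was not called is not shown to be unbound.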

Other observations

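The tests on cardiac genes and on neighbouring genes were chosen after the result was seen, and all genes in this part were chosen after their values were seen. Outside the lists, Eif4ebp2, which encodes a repressor of cap-dependent translation, had the most enriched 3′ UTR peaks. There were 11, between 61429577 and 61431783 on chromosome 10, with a median log2 fold change of 4.81 in the authors' deposited table. Peak1, a pseudokinase of the cytoskeleton, followed with 6 enriched 3′ UTR peaks out of 6 (median 3.23 in the authors' deposited table). In the other direction, Klhdc3, Srf, the serum response factor, and Slc4a2, an anion exchanger, were depleted in 9 of 9 peaks each, with medians of -3.86, -4.07 and -2.26 in the authors' deposited table.

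Coding and untranslated-region peaks were tested in 49 of 50 cardiac muscle genes, although MLTC-1 is a Leydig line. Titin (Ttn) alone had 566, of which 18 were enriched and 1 depleted, and Ryr2, the cardiac calcium release channel, had 102 with 12 enriched. Heart RNA in the IgG library alone would place these genes low. Their median of 0.37 lay at the percentile 100 of 10000 random lists matched on peaks per gene (median -0.60). The list was drawn up after its values were seen, and the direction of the fold change is assumed. The percentile therefore cannot exclude that source. A general presence of tissue-restricted transcripts would show in fast skeletal muscle, hepatocyte and neuronal genes too. Of these, 12 of 75 (16%, exact 95% binomial interval 8.55 to 26.3) had such peaks against 34.9% of all protein-coding genes. The lists differed, with 8 of 25 neuronal genes (32%), 4 of 25 fast skeletal muscle genes (16%) and 0 of 25 hepatocyte genes. None came near the 98% of the cardiac list. Heart RNA in the ZFP36L2 libraries alone stays open too, because the answer changed with the scaling. Of the 1329 cardiac peaks, 24.8% had a log2 fold change of 1 or more as deposited (interval 21.5 to 32.1), but 62.5% did after centring (54.9 to 67.6). The deposited share was 8.67% for all protein-coding genes, 21.7% for cardiac fibroblast genes, 23.5% for fast skeletal muscle genes (17 peaks) and 0% for neuronal genes (16 peaks). Their centred shares were not computed. Among the cardiac peaks, 58 were called enriched and 7 depleted, and without depth the uncalled ones cannot decide. Heart RNA in both kinds of library and transcription by the line itself may also account for the cardiac peaks and were not tested. Coding or untranslated-region peaks were also tested in 19 of 20 cardiac fibroblast genes, many of which other mesenchymal cells express.

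Among the best coding peaks were several genes of proteins with long acidic stretches, such as Anp32b with 14 of 14 peaks enriched and Hmgn5 with 8 of 8. As a hypothesis, a purine-rich coding sequence may favour recovery with ZFP36L2, so a second list of such genes was written before their values were looked up. Of its 17 members with a coding peak, 4 (Cenpb, Eif5b, Pelp1 and Rsf1) had an enriched one, against 4.37% of 6202 other genes (permutation p = 0.0118 at the same number of coding peaks). Random genes with as many coding peaks gave 0.757 on average and 2 at the 95th percentile, which argues against the number of tested peaks as the cause. The sequences themselves were not read and transcript level could not be matched, so the property these genes share stays open, and no biological explanation was tested.

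Depleted peaks seemed to crowd in neighbouring genes, as on chromosome 17 from 46543745 to 46687649, where 28 peaks in 6 genes (Cul9, Klc4, Klhdc3, Ppp2r5d, Ptk7 and Srf) were depleted, all on the minus strand. The window of 250000 nucleotides that holds them had 50 peaks. In the windows with the next most depleted peaks, those on the plus and minus strands numbered 14 and 2 (chromosome 5), 1 and 13 (chromosome 7), 14 and 0 (chromosome 8) and 10 and 2 (chromosome 15). Across the genome, both genes had a depleted peak in 183 of 6611 adjacent pairs against 190 from permuted calls (permutation p = 0.720). For pairs of genes, that is the level chance placement gives. The test counts a gene from its first depleted peak on, so it cannot assess dense stretches of depleted peaks such as these. Among gene pairs, readthrough from one gene into the next cannot be told apart from chance, because there was no excess to divide between strands. Within dense stretches, readthrough was not tested. Pairs on opposite strands stood at 0.957 times the permuted mean and pairs on the same strand at 0.972.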
